A study of Megalobrama amblycephala with 2 samples.

How the data were processed

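Cells of dorsal skeletal muscle of the blunt snout bream, Megalobrama amblycephala, a farmed freshwater fish, were profiled by droplet single-cell RNA sequencing with 1 library from fish aged 30 days and 1 from fish aged 45 days. Per the labels' protocols, the tissue was minced on ice, freed of blood and fat, digested with shaking in a warm bath, strained, treated with a red blood cell lysis buffer and loaded on the 10x Genomics 3' kit version 3.1. The labels do not say how many fish went into a library, nor at what hour they were sampled. The deposited matrices hold raw UMI counts per gene and cell barcode, made with Cell Ranger 6.0 per the submitters' processing notes and 6.0.0 per the file headers. The genome build and annotation used for counting are not given in the sources used here, so no coordinates are printed.

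The files listed 37071 features, of which 24 carried no gene name. These held 5.00% of UMIs at day 30 and 7.22% at day 45 and were left out of library sizes and comparisons. Of the 37047 features used, 18288 had a locus number only and 18759 had a symbol. The NCBI table of the assembly ASM1881202v1, which lists 36365 symbols, was used only to look up names; it gives no product names, so genes with a locus number alone are not named. Mitochondrial transcripts were counted from 13 genes.

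Cells were kept with at least 500 UMIs, at least 200 genes and at most 20% mitochondrial UMIs. Of the barcodes at day 30, 275 had under 500 UMIs, 82 under 200 genes and 566 over 20% mitochondrial UMIs, counted separately; the numbers at day 45 were 658, 30 and 256. Doublets were called per library with Scrublet, as run by scanpy 1.11.5, at an expected rate of 0.8% per 1000 barcodes. It marked 71 barcodes at day 30 (1.12%, with 5.06% expected) and 452 at day 45 (4.11%, with 8.79% expected), which were removed, so some doublets may remain. The filters left 5556 of 6322 barcodes at day 30 and 9701 of 10985 at day 45.

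Counts were scaled to 10000 per cell and log-transformed, and 30 principal components of 2000 variable genes were taken from both libraries together without integration. A graph of 20 nearest neighbours was clustered with Leiden at resolution 0.8 (leidenalg 0.10.2, igraph 0.11.9). The other packages were numpy 2.4.6, scipy 1.17.1, scikit-learn 1.9.0, pandas 2.3.3 and matplotlib 3.10.9 under Python 3.11.15. Clusters were named from 21 lists of cell type markers, of which 335 genes were found. A cluster took a name with at least 3 markers that were at least 2-fold higher than in other cells and present in at least 10% of its cells, unless its 10 leading genes held more markers of another class than of its own. Cluster 15 had 3 markers of the T or NK cell list but stayed unnamed for that reason. A cluster whose median depth in a library was under that of the library divided by 3 also needed 1 of its own markers among those genes. These thresholds, and the joining of the fibroblast and tenocyte lists into 1 connective-tissue class, were set after the data were seen; the markers themselves were not. Names rest on transcripts alone and are therefore written as "-like". A cluster that comes mostly from 1 library may be that library, not a cell type.

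With 1 library per age there are no replicates, and cells are not replicates of an animal, so no test was run and no difference between the ages has a replicate check. Raw counts were summed over all cells and over each class with at least 50 cells in both libraries, which gave 7 comparisons. They are given as ratios, day 45 over day 30, of counts scaled to the same total of UMIs (CPM), with exact conditional binomial 95% intervals. Shares of cells have exact Clopper-Pearson 95% intervals. All intervals, and the limit of 3 counts set beside a count of 0, cover counting error only. A gene was counted as higher or lower where the sums differed at least 2-fold with at least 100 UMIs over both libraries, which is a description of size.

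The genes named are from the 10 with the highest and the 10 with the lowest ratio among genes with a symbol, at least 100 UMIs and a UMI in at least 10% of the class's cells in the library where the gene was higher. In that library the gene also had to reach at least 0.2 times its highest CPM in any class. For the endothelial-like, mural-like and myocyte-like classes the first 3 each way are named. This last condition does not apply to all cells together. The genes sdk2b in connective-tissue-like cells and s100b in Schwann-like cells met the rule but lead a cluster of their class, so they are not given as results, and neither are list members that lead a cluster of the class compared. For 22 gene lists, the median log2 ratio of members with at least 20 UMIs was set among 10000 random lists of the same size matched on mean expression. The percentile describes these libraries only. List members named as examples are among the 4 with the most UMIs. Lists with fewer than 5 measured members in a class have no value there. The lists, the markers, the rule for named genes, the filters, the fixed cycling measure and 14 alternatives were chosen before the data were examined.

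The lists cover DNA replication and G1/S, mitosis and G2/M, myogenic regulators, myoblast fusion, the fast sarcomere, the slow and cardiac sarcomere, Z-disc and sarcomere assembly, calcium handling and excitation, glycolysis and phosphocreatine, nuclear genes of oxidative phosphorylation, and fibrillar and muscle matrix. They also cover IGF, myostatin and growth signalling, dissociation stress and immediate-early genes, the unfolded protein response and hypoxia, antigen presentation, interferon response, inflammatory cytokines, lipid uptake and storage, angiogenesis and endothelial genes, haemoglobin, cytosolic ribosomal proteins and mitochondrially encoded genes.

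Shares of cells with cell cycle or myogenic transcripts were compared after thinning each cell to 1000 UMIs, since the libraries differed in depth; shallower cells were left out. A cell counted as cycling with at least 2 UMIs of the mitosis and G2/M list, and as positive for a myogenic gene with at least 1 UMI. A narrow list of 41 of the 47 mitosis genes, without tubulin, stathmin, high-mobility-group, histone and bub3 genes, was added after the data were seen. So were the sets of clock and chaperone genes, the genes described in fibres and the cells with apoeb.

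The alternatives were a minimum of 500 genes per cell, at most 10% mitochondrial UMIs, doublet calls kept, Leiden resolutions of 0.4 and 1.5, and centring of each gene within each library. For ratios they were scaling by the trimmed mean of M-values, scaling without the 50 most abundant genes, and the mean over cells. For counts of genes they were a minimum of 20 UMIs, and no minimum with 1 UMI added. For shares they were thinning to 500 or 2000 UMIs, and at least 1 UMI of the list. The 6 added after seeing the data were the narrow mitosis list, clustering without 616 cell cycle genes, leaving out connective-tissue-like clusters with at least 85% of cells, weighted by library size, from 1 library, Schwann-like cluster 6 alone (the Schwann-like cluster with the highest share of cells in the library where it was rarer), and the cycling share by the full list and by the narrow list without doublet calls and the mitochondrial filter.

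The computations were tested on simulated data. For all cells, counts were drawn from the observed sums with 200 genes changed by known folds. All 50 genes set 4-fold higher and all 50 set 4-fold lower were counted, and 0 of the 50 set 1.5-fold higher, 0 of the 50 set 1.5-fold lower and 0 of 14717 unchanged genes were. Of 14914 intervals, 95.4% held the simulated ratio. The trimmed mean recovered a log2 shift of -0.006 where -0.007 was simulated. That shift is far smaller than those found in the data, such as 0.69 in myocyte-like cells, so the trimmed mean was not tested at such sizes. Of 440 list percentiles with no change simulated, over 19353 genes, 4.32% lay outside the 2.5th to 97.5th percentile, and the mitosis list of 46 genes set 2-fold lower gave a median of -1.00. With equal cycling shares simulated in 1000 cells per library at the observed depths, the ratio of shares was 0.928 without thinning and 1.04 with it.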

Results

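The data describe cells of dorsal skeletal muscle at 2 ages, 30 and 45 days, chosen by the submitters as a period of rapid making of new fibres (hyperplasia) and growth of fibres (hypertrophy). The day 30 library held 30323443 UMIs in 6322 barcodes and the day 45 library 32212434 UMIs in 10985 barcodes. Kept cells had a median of 2710.5 UMIs and 1124.5 genes at day 30 and of 1671 UMIs and 785 genes at day 45. Mitochondrial genes took a median of 3.08% and 2.68% of their UMIs. With 1 library per age, the values below compare those libraries, and no difference has a replicate check.

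The first question was which cells the muscle yielded at each age. Muscle stem cell-like cells, which hold pax7a, pax7b and myf5, made up 8.35% of cells at day 30 (95% interval 7.64 to 9.11) and 18% at day 45 (17.3 to 18.8), a ratio of 2.16 (1.95 to 2.40). Myocyte-like cells, with myog, mymk and actc1a, were 1.57% and 3.45%, and fast fibre-like cells 0.774% and 1.39%. Endothelial-like cells were fewer at day 45, 5.02% against 10.4%, a ratio of 0.483 (0.428 to 0.546). Connective-tissue-like cells were the most numerous class at both ages, with 44.3% and 40.4%, followed by Schwann-like cells with 16.9% and 20.5%. Mural-like cells, the contractile cells around vessels, were 4.52% and 4.75%, and erythroid-like cells were 2 cells (0.0360%) and 50 cells (0.515%). Dissociation, straining and red cell lysis can set such shares.

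**Figure D1:**
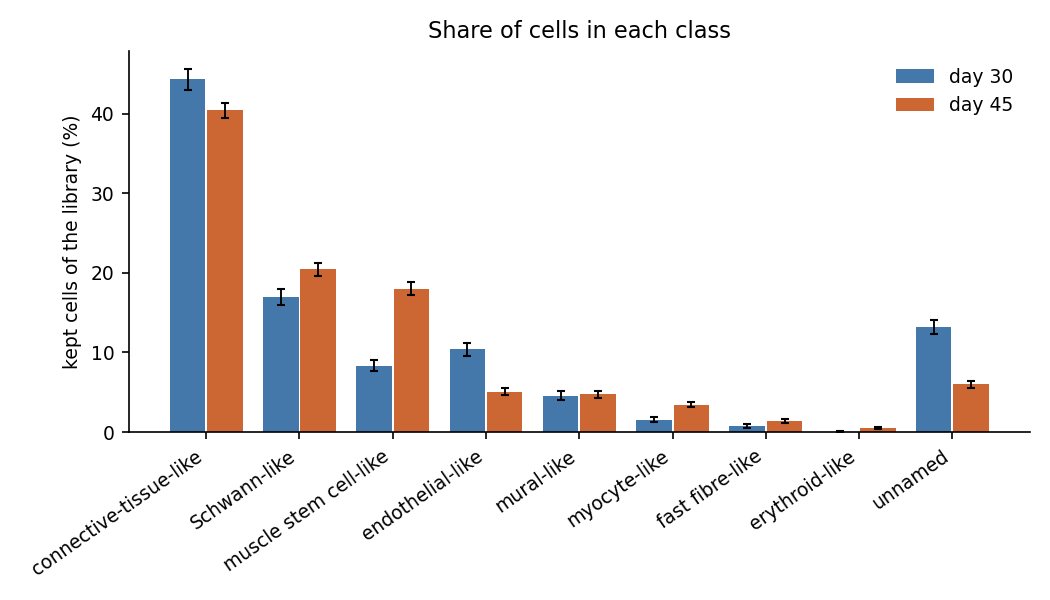
Share of the kept cells of each library (percent) in each marker-named class at day 30 and day 45; error bars are exact 95% binomial intervals for counting error. Muscle stem cell-like cells made up 8.35% at day 30 and 18% at day 45, and endothelial-like cells 10.4% and 5.02%.

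The classes came from 24 clusters, of which 21 were named. The unnamed clusters 14, 15 and 18 held 13.1% of cells at day 30 and 5.98% at day 45. Cluster 14 was led by cell division genes and held 464 cells at day 30 and 46 at day 45. Cluster 15 was led by immune genes, among them il13 and fcer1g, and held 157 and 330 cells, and cluster 18 held 109 and 204. Some named clusters were led by stress or immune genes as well. The gene cryabb led Schwann-like cluster 1, and il15 was among the leaders of stem cell-like cluster 2. Those of connective-tissue-like cluster 10 included cxcl8b.3, ccl25b and cxcl12a. Myocyte-like cluster 16 was led by hsp90aa1.1, a myosin chaperone gene of the Z-disc and sarcomere assembly list, followed by the myocyte markers actc1a, unc45b and myog. The genes mrc1a, mrc1b and mafbb, the last of them on the macrophage marker list, were among the leaders of endothelial-like cluster 23. So were prox1a and stab1 of the endothelial marker list, and the cluster also held flt4, lyve1a and stab2.

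Summed over all cells, 3 of the 10 named genes highest at day 45 belong to the circadian clock. The clock repressor nr1d1 was 16.7-fold higher at day 45 (15.6 to 17.9; 820 and 13655 UMIs), per1b, a period gene, 10.8-fold (9.78 to 12), and the cryptochrome cry2 8.37-fold (7.79 to 9.01). The complement component c4 was 11.6-fold higher (10.4 to 12.9), hspbp1, which encodes a partner of the chaperone HSP70, 8.47-fold (7.63 to 9.43), and the methionine adenosyltransferase gene mat2ab 8.05-fold. The other genes at the high end were si:ch211-132b12.7 (22.0-fold), znf395b (14.3), wbp2 (11.4) and si:dkey-211g8.8 (8.79). Lowest was fkbp11, 12.6-fold lower at day 45 (10.5 to 15.3; 1554 and 123 UMIs), then pdia4, 9.51-fold (7.88 to 11.6), and gpx7 (9.39), vkorc1 (8.63), rcn3 (7.40) and calr (6.76) followed. Also lower were cry3b, another cryptochrome gene (7.07-fold), the secreted protease gene htra1a (7.52), the tubulin-binding stathmin stmn1a (6.47) and mxd3 (6.27).

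In all cells 1232 of 14798 genes were at least 2-fold higher at day 45 and 1981 at least 2-fold lower, so 38.3% of these were higher; scaled by the trimmed mean of M-values, 1575 were higher and 1558 lower, or 50.3%. That scaling raised the log2 ratios of all cells by 0.14, of Schwann-like cells by 0.10, of stem cell-like cells by 0.26, of endothelial-like cells by 0.17 and of myocyte-like cells by 0.69. In these classes most list medians are therefore also given relative to it ("trimmed mean"). None of the genes named for its size changed direction under the other scalings tried.

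Genes of cell division were lower at day 45 in the sum of all cells. Medians of lists are set among 10000 random lists of genes of similar expression, which describes these libraries only. Of the 34 genes for DNA replication, 28 were lower and 0 higher, with a median log2 ratio of -1.67 (trimmed mean -1.53), below every one of the random lists. Among them pcna, the clamp of DNA polymerase, was 3.43-fold lower, and rrm1, a subunit of ribonucleotide reductase, 3.63-fold. Of the 46 mitosis genes 44 were lower and 0 higher (median -2.97, trimmed mean -2.82), with hmgb2b 3.17-fold lower. Cluster 14, which is led by such genes, held 8.35% of cells at day 30 and 0.474% at day 45.

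Fast and slow contractile genes differed in direction in the sum of all cells. Of 18 fast sarcomere genes 14 were higher and 3 lower (median 1.35, trimmed mean 1.49, above all random lists), with actc1b 3.55-fold, mylz3 4.10-fold and tpma 5.24-fold higher. Of 15 slow and cardiac sarcomere genes 0 were higher and 10 lower (median -2.09, trimmed mean -1.95, below all random lists). Among them tpm3 was 2.00-fold lower, tpm2 4.27-fold, myl10 4.48-fold, and myl2a had 722 UMIs at day 30 and 5 at day 45. At day 30, 13 fast fibre-like cells held 87.1% of the myl2a UMIs and 17 held 69.1% of those of myl10. Such cells held only 26.5% of the tpm2 UMIs. For part of the list the difference therefore rests on few cells. The Z-disc list had 16 of 36 genes higher and 6 lower (median 0.89, trimmed mean 1.03), with the myosin chaperone gene hsp90aa1.1 8.48-fold higher, but its median was -0.29 when each cell was weighted alike. Calcium handling had 13 of 31 genes higher and 2 lower (median 0.82, trimmed mean 0.96), with the calcium buffers pvalb1 5.23-fold and pvalb4 4.34-fold higher and asph 5.36-fold lower. Glycolysis and phosphocreatine had 7 of 33 higher and 2 lower (median 0.27, trimmed mean 0.41, percentile 99.4), with the creatine kinases ckma 3.63-fold and ckmb 3.48-fold higher. Fast fibre-like cells, whose share had a ratio of 1.80, or 1.05 with at least 500 genes per cell, held 46.2% of the actc1b UMIs at day 30 and 83.5% at day 45, and when each cell was weighted alike the fast sarcomere median was 0.25. Myogenic regulators (7 of 30 higher, 2 lower, median 0.02) and fusion genes (3 of 25 higher, 0 lower, median 0.08) lay at percentiles of 83.5 and 87.5.

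Nuclear genes of oxidative phosphorylation were lower, 15 of 47 by at least 2-fold and 0 higher (median -0.78, trimmed mean -0.64, below all random lists), with atp5f1b 1.72-fold lower. Matrix genes had 2 of 52 higher and 9 lower (median -0.33, trimmed mean -0.19, percentile 0.06); the collagen genes col1a2 and col1a1a were 1.78-fold and 1.75-fold lower. Angiogenesis genes had 0 of 27 higher and 15 lower (median -1.03, trimmed mean -0.89, below all random lists), with sox7 2.09-fold lower and cldn5b 1.47-fold higher, beside the smaller share of endothelial-like cells. IGF and growth signalling had 3 of 45 higher and 4 lower (median 0.07, percentile 96.2), with fstl1b 1.9-fold lower.

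Of the stress and immune lists, the immediate-early and interferon lists were the ones above all random lists. Of 43 dissociation stress and immediate-early genes 18 were higher and 0 lower (median 0.78, trimmed mean 0.92, above all random lists), with fosab 1.96-fold and jun 2.07-fold higher. Of 18 interferon response genes 9 were higher and 0 lower (median 0.94, trimmed mean 1.08, above all random lists), with the signal transducers stat1a 2.36-fold and stat2 3.01-fold higher. The unfolded protein response list divided, with 2 of 31 higher and 11 lower (median -0.33, trimmed mean -0.19, percentile 8.28): the transcription factor genes atf4a, atf4b and ddit3 were 2.36-fold, 2.01-fold and 1.76-fold higher, while pdia4 and calr were among those lowest. Inflammatory cytokines had 5 of 20 higher and 4 lower (median 0.15, percentile 91.8), with the chemokine genes cxcl18b 3.45-fold higher and cxcl12b 2.82-fold lower. Antigen presentation had 0 of 9 higher and 1 lower (median 0.13, percentile 85.8). Lipid uptake and storage had 5 of 22 higher and 2 lower (median 0.14, percentile 93.3), with the lipid droplet gene plin2 2.62-fold higher and the fatty acid binding gene fabp4a 3.64-fold lower. Haemoglobin genes (4 of 7 higher, 2 lower, median 1.27) included hbba2 2.89-fold higher and hbbe2 3.46-fold lower, and their median was -0.46 with at least 500 genes per cell. None of 81 ribosomal protein genes (median -0.04, which became 0.10 under the trimmed mean) or 13 mitochondrially encoded genes (median -0.26, trimmed mean -0.11) differed 2-fold.

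**Figure D2:**
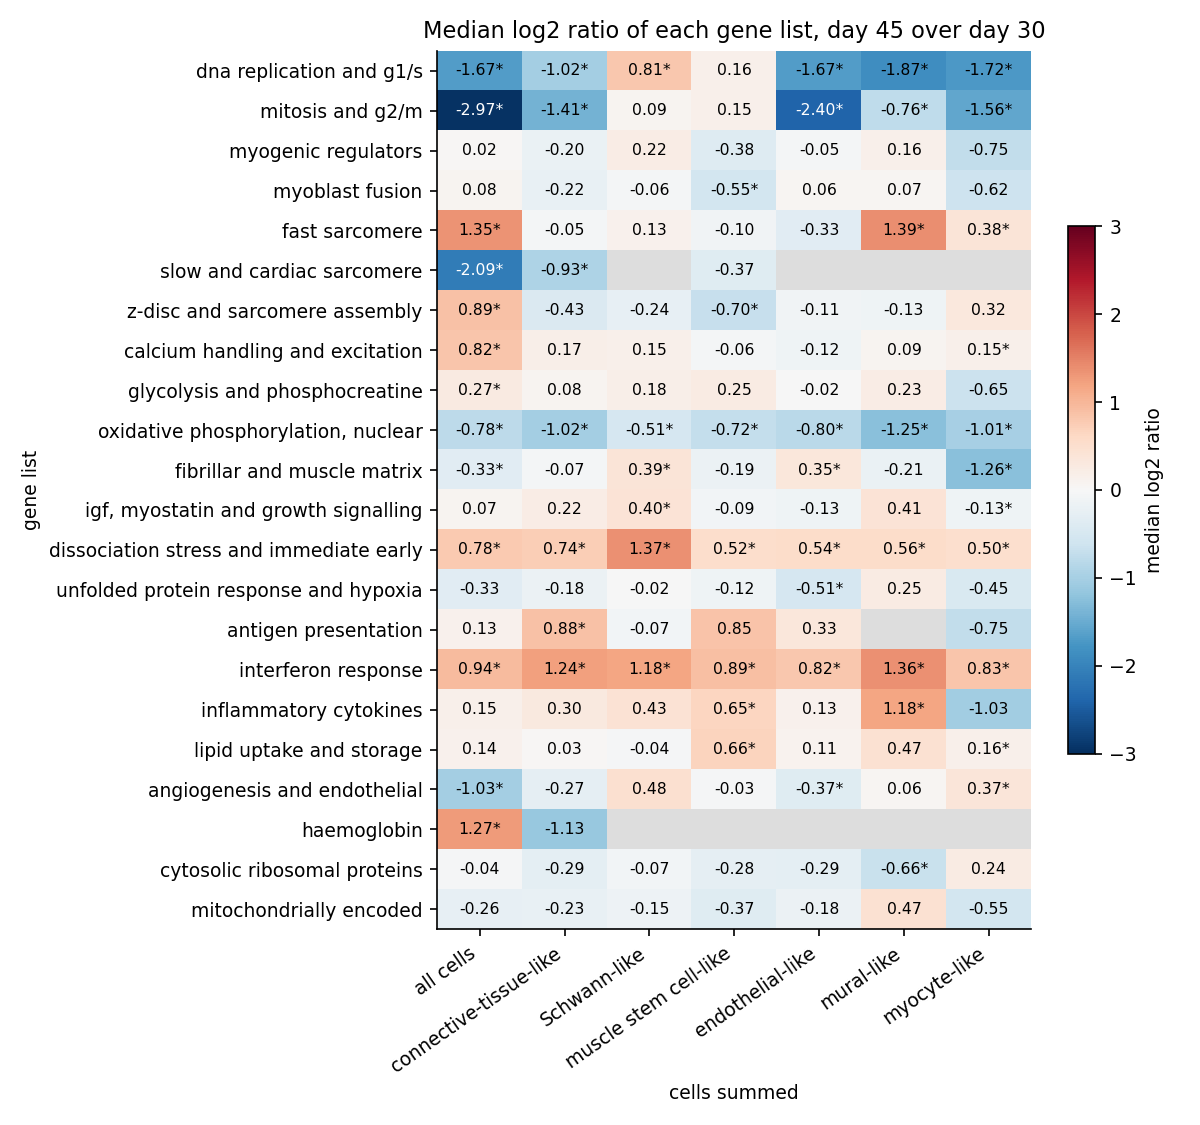
Median log2 ratio of scaled counts (CPM), day 45 over day 30, of each fixed gene list (vertical axis) in the sum of all cells and of each class (horizontal axis), scaled to total UMIs; an asterisk marks a median among the lowest or highest 2.5% of 10000 matched random lists, and grey marks lists with fewer than 5 measured members. The immediate-early list was positive in every column, from 0.50 in myocyte-like to 1.37 in Schwann-like cells, and signs of small medians, such as -0.13 for growth signalling in myocyte-like cells, which became 0.56 under the trimmed mean, depended on scaling.

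Within connective-tissue-like cells the clock genes were again far apart: nr1d1 was 20.2-fold (18.2 to 22.5), per1b 17.2-fold (14.3 to 20.9), cry2 9.83-fold and ciarta, a clock-associated repressor, 9.55-fold higher at day 45. The co-chaperone gene dnajb1b was 7.82-fold higher (7.60 to 8.03; 5941 and 39071 UMIs), and si:ch211-132b12.7 (25.3-fold), znf395b (15.8), si:dkey-211g8.8 (10.3), mat2ab (10.2) and c4 (10.1) were also at the high end. At the low end fkbp11 was 18.4-fold (13.8 to 25), pdia4 13.8-fold (10.1 to 19.2), manf 12-fold, dad1 10.0-fold and calr 9.91-fold lower. The beta-tubulin gene tubb5 (12.6-fold), mxd3 (11.8), the actin-nucleating complex gene arpc5a (10.9) and cry3b (10.4) were lower too. At least 2-fold higher were 1012 of 10536 genes and lower 1257 (44.6% higher), against 1181 and 1079 under the trimmed mean (52.3%). Clusters 10 and 11 held 592 and 520 of the 2461 cells at day 30, and cluster 5 held 1129 of the 3920 at day 45. Each came mostly from 1 library, and without them 1065 genes were higher and 628 lower. The ratios of pdia4 and manf were then 0.116 and 0.156. Medians of depth were 4467 and 2175.5 UMIs.

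Among the lists in these cells, oxidative phosphorylation (25 of 47 lower, 1 higher, median -1.02), DNA replication (15 of 30 lower, 0 higher, median -1.02) and mitosis (23 of 37 lower, 1 higher, median -1.41) lay below all random lists. The immediate-early list (16 of 42 higher, 0 lower, median 0.74) and interferon response (8 of 15 higher, 0 lower, median 1.24) lay above all of them; egr1 was 2.36-fold and stat2 3.32-fold higher. Antigen presentation had 4 of 8 genes higher and 1 lower (median 0.88, percentile 99.6), with b2ml, a beta-2-microglobulin gene, 2.31-fold and the invariant chain gene cd74b 2.51-fold higher. The unfolded protein response list was not extreme (4 of 31 higher, 13 lower, median -0.18, percentile 21.9). Without the clusters mostly of 1 library the mitosis median was -0.56 and the antigen presentation median 1.54, and clustered without cell cycle genes the mitosis and replication medians were -5.23 and -2.76. Slow sarcomere genes had 3 of 7 lower (median -0.93, percentile 2.48). The matrix list, the main product of these cells, had 3 of 52 genes higher and 8 lower with a median of -0.07 that became 0.01 under the trimmed mean; col1a2 was 1.38-fold and sparc 1.21-fold lower.

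Within Schwann-like cells, the glia of nerves, nr1d1 was 22.7-fold (17.7 to 29.7), the period gene per3 15.4-fold, per1b 8.97-fold and cry2 7.65-fold higher at day 45. Chaperone-related genes were higher with them: the co-chaperones bag3 10.9-fold (7.99 to 15.2) and dnaja 9.23-fold, hspbp1 7.5-fold and the stress-inducible zfand2a 7.35-fold. The kinase gene pim2 (7.57-fold) and si:dkey-211g8.8 (15.2) completed the high end. Lower genes were less far apart: the DNA ligase gene lig1 was 4.55-fold (3.41 to 6.15), stk17a 4.24-fold, rab6bb 4.18-fold, mid1ip1b 3.70-fold, si:ch211-156j16.1 3.60-fold, ube2na 3.49-fold and gstt1b 3.47-fold lower. At least 2-fold higher were 516 of 5365 genes and lower 253 (67.1% higher), against 602 and 153 under the trimmed mean (79.7%). Cluster 6 held 811 of 941 cells at day 30 and cluster 1 held 1483 of 1984 at day 45. In cluster 6 alone 146 genes were higher and 232 lower. Of the genes named above, bag3 was 4.2-fold, dnaja 1.83-fold, hspbp1 2.57-fold, zfand2a 3.00-fold and pim2 4.82-fold higher in cluster 6 alone. There lig1 and ube2na had ratios of 0.612, gstt1b 0.759 and si:ch211-156j16.1 0.114. Of cluster 6 itself, 13.7% came from day 45 when weighted by library size, so it is uneven too. Medians of depth were 1579 and 1068 UMIs.

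Immediate-early genes showed their highest median in this class, with 28 of 40 higher and 0 lower (median 1.37, trimmed mean 1.48), and fosab was 2.67-fold higher. Interferon response also lay among the highest 2.5% of random lists (11 of 15 higher, 0 lower, median 1.18, trimmed mean 1.28). So did DNA replication (8 of 22 higher, 0 lower, median 0.81, trimmed mean 0.91) and matrix genes (10 of 45 higher, 0 lower, median 0.39, trimmed mean 0.49). Unscaled, pcna had 67 and 149 UMIs, of class totals of 1771843 and 2631293. Growth signalling had 7 of 31 higher and 1 lower (median 0.40). In cluster 6 alone the medians were 0.58 for immediate-early, 0.47 for interferon, 0.46 for matrix and -0.20 for growth signalling genes, and too few replication genes were measured for a value. Oxidative phosphorylation had 2 of 46 lower and 0 higher (median -0.51, trimmed mean -0.41, percentile 0.01), with a median of -0.06 in cluster 6 alone.

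Within muscle stem cell-like cells, the reserve from which new muscle nuclei come, nr1d1 was 18.9-fold (14.4 to 25.3), per1b 9.83-fold (6.98 to 14.3) and the HSP110-family gene hspa4a 9.36-fold higher at day 45. The chemokine gene cxcl8a was 11.9-fold higher (7.25 to 21.0; 16 and 538 UMIs), the alpha-tubulin gene tuba8l2 11.2-fold (5.28-fold clustered without cell cycle genes) and hopx 9.04-fold, while si:ch211-132b12.7 (21.4-fold), pnp5b (21.1), znf395b (18) and mapre3b (12) rested on 8 UMIs or fewer at day 30. At the low end mxra5a was 16.1-fold lower (13.4 to 19.4; 797 and 140 UMIs), followed by cry3b (12.2-fold), csrp1b (11.8), the secreted Wnt antagonist frzb (10.2), stk17a (6.28), cd82a (6.20), brinp2 (6.05), prkcsh (5.81), atoh8 (5.66) and rcn3 (5.32). At least 2-fold higher were 614 of 5394 genes and lower 464 (57.0% higher), against 935 and 247 under the trimmed mean (79.1%). Clusters 2 and 9 made up the class at both ages, with medians of 2787 and 2169 UMIs.

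Immediate-early genes had 14 of 41 higher and 0 lower in stem cell-like cells (median 0.52, trimmed mean 0.78), with atf3 2.67-fold higher. Interferon response (4 of 13 higher, 0 lower, median 0.89, trimmed mean 1.15), inflammatory cytokines (6 of 17 higher, 2 lower, median 0.65, trimmed mean 0.91; cxcl18b 3.74-fold higher) and lipid uptake and storage (6 of 16 higher, 1 lower, median 0.66, trimmed mean 0.92) also lay among the highest 2.5% of random lists; plin2 was 4.03-fold and the fatty acid synthase gene fasn 2.12-fold higher. Oxidative phosphorylation (12 of 46 lower, 0 higher, median -0.72, trimmed mean -0.46), Z-disc genes (5 of 15 lower, 3 higher, median -0.70, trimmed mean -0.44) and fusion genes (4 of 21 lower, 2 higher, median -0.55, trimmed mean -0.29) lay among the lowest 2.5%. Myogenic regulators had 2 of 27 higher and 3 lower (median -0.38, percentile 5.27); id1 and id3 were both 1.94-fold lower. The replication and mitosis lists had medians of 0.16 and 0.15 in this class, and the mitosis list had 0.09 in Schwann-like cells. Cluster 14, led by cell division genes, is not part of these classes.

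Within endothelial-like cells hspbp1 was 17.3-fold (11.6 to 27.0), si:ch211-132b12.7 12-fold and wbp2 11.6-fold higher at day 45, and cry3b was 7.21-fold (4.33 to 12.9), the neuropilin gene nrp1b 6.42-fold and the apelin gene apln, a ligand in vessel growth, 6.39-fold lower. At least 2-fold higher were 307 of 4636 genes and lower 470 (39.5% higher), against 418 and 278 under the trimmed mean (60.1%). Mitosis genes (21 of 27 lower, 0 higher, median -2.40, trimmed mean -2.23, or -1.26 with at most 10% mitochondrial UMIs) and replication genes (17 of 22 lower, 0 higher, median -1.67, trimmed mean -1.49) lay below all random lists, as did oxidative phosphorylation (14 of 46 lower, 0 higher, median -0.80, trimmed mean -0.62). The angiogenesis list had 7 of 25 lower and 3 higher (median -0.37, trimmed mean -0.19, percentile 1.83), with the transcription factor gene sox7 1.29-fold lower, and the unfolded protein response list 10 of 29 lower and 2 higher (median -0.51, trimmed mean -0.34, percentile 1.75). Among the highest 2.5% lay immediate-early genes (10 of 40 higher, 0 lower, median 0.54, trimmed mean 0.72), interferon response (5 of 13 higher, 1 lower, median 0.82, trimmed mean 0.99) and matrix genes (8 of 46 higher, 6 lower, median 0.35, trimmed mean 0.52), although the basement membrane gene col4a1 was 2.59-fold lower. Cluster 8 held most of the class at both ages, 490 of 577 and 278 of 487 cells, while cluster 20 held 44 and 133, with class medians of 2102 and 1409 UMIs.

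Within mural-like cells si:dkey-211g8.8 was 28.8-fold (13.6 to 72.9; 7 and 143 UMIs), per3 12.3-fold and nr1d1 9.64-fold higher at day 45, and calr3b was 7.52-fold (4.42 to 13.7), cry3b 7.31-fold and selenoh 5.67-fold lower. At least 2-fold higher were 298 of 2424 genes and lower 182. Lists among the lowest 2.5% were replication (15 of 16 lower, 0 higher, median -1.87), oxidative phosphorylation (31 of 46 lower, 0 higher, median -1.25) and mitosis (3 of 6 lower, 0 higher, median -0.76). Ribosomal proteins lay there too (0 of 80 by 2-fold, median -0.66). The random lists matched to them had a median of -0.55, so most of that value is shared by genes of similar expression. The mitosis median was -2.82 clustered without cell cycle genes. Among the highest 2.5% were interferon response (5 of 8 higher, 0 lower, median 1.36), inflammatory cytokines (5 of 10 higher, 0 lower, median 1.18) and immediate-early genes (10 of 41 higher, 0 lower, median 0.56). Fast sarcomere genes had 8 of 11 higher and 0 lower (median 1.39) at low counts, such as 31 and 77 UMIs of mylz3, beside a share of fast fibre-like cells that was also higher at day 45 but not with at least 500 genes per cell (ratio 1.05). Cluster 12 held 194 of 251 cells at day 30 and 348 of 461 at day 45, and class medians were 3986 and 1302 UMIs.

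Within myocyte-like cells, all from cluster 16, snx22 was 9.65-fold (3.68 to 35.9; 4 and 136 UMIs) and the co-chaperone gene dnajb2 8.48-fold higher at day 45, and mxra5a was 31.2-fold (17.9 to 58.7; 124 and 14 UMIs), lsp1b 9.20-fold and the dynein light chain gene dynll1 8.99-fold lower. These sizes depended on settings: clustered without cell cycle genes mxra5a had a ratio of 0.0923 and dynll1 0.249, and under the trimmed mean lsp1b had 0.176 and dynll1 0.180. The actin gene acte1 was 9.26-fold higher here but lower under 6 of the alternatives, from 0.118 to 0.873 of its day 30 level. This class moved most with scaling: 184 of 2469 genes were at least 2-fold higher and 535 lower (25.6% higher), against 512 and 142 under the trimmed mean (78.3%) and 227 and 403 without the 50 most abundant genes (36.0%). Under both the total and the trimmed mean, replication (24 of 27 lower, 0 higher, median -1.72, trimmed mean -1.02), mitosis (8 of 12 lower, 0 higher, -1.56 and -0.86), matrix (27 of 44 lower, 3 higher, -1.26 and -0.57) and oxidative phosphorylation genes (24 of 46 lower, 0 higher, -1.01 and -0.31) had negative medians. Immediate-early genes (10 of 40 higher, 2 lower, 0.50 and 1.2), interferon response (4 of 9 higher, 0 lower, 0.83 and 1.53), fast sarcomere genes (4 of 10 higher, 1 lower, 0.38 and 1.08) and angiogenesis genes (1 of 5 higher, 1 lower, 0.37 and 1.06) had positive medians under both. The medians of calcium handling (2 of 14 higher, 1 lower, 0.15) and lipid genes (2 of 14 higher, 2 lower, 0.16) became -0.027 and -0.070 when genes were centred within each library, and that of growth signalling (2 of 30 higher, 7 lower, -0.13) became 0.56 under the trimmed mean. The creatine kinase gene ckma was 3.12-fold higher and the type I collagen gene col1a2 3.1-fold lower, and medians of depth were 9712 and 9025 UMIs.

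Clock output and chaperone genes, sets drawn up after these results were seen, were higher at day 45 in each of the 6 classes compared. Since the members were chosen with the values known, this direction is not a separate result. Genes outside the sets went the other way, such as the cryptochrome gene cry3b. So did pdia4, manf and calr of the unfolded protein response list in connective-tissue-like cells. The 5 clock genes nr1d1, per1b, per3, cry2 and ciarta had median log2 ratios from 1.79 in myocyte-like to 3.30 in connective-tissue-like cells. The 8 chaperone and proteotoxic stress genes, among them dnajb1b, bag3, hspa4a, ubb and sqstm1, had medians from 1.93 in myocyte-like to 2.61 in connective-tissue-like cells.

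**Figure D3:**
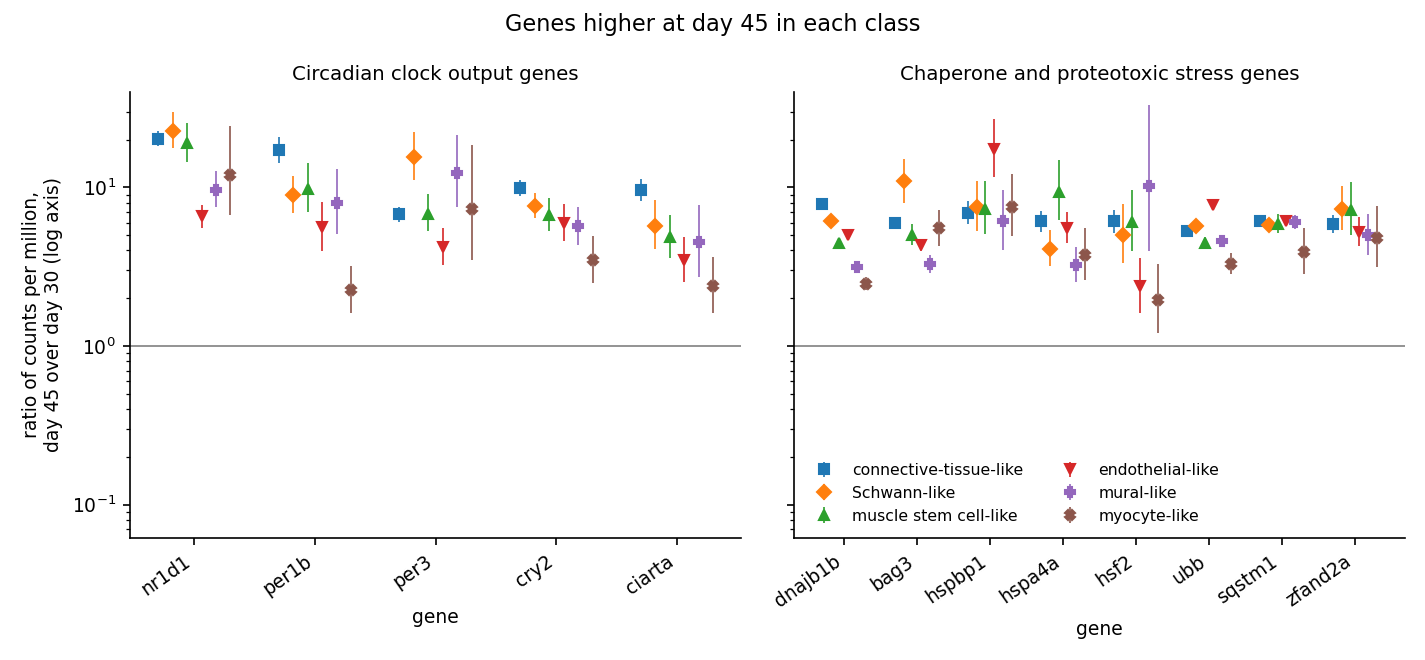
Ratio of scaled counts (CPM), day 45 over day 30 (log axis), of 5 clock output genes and 8 chaperone genes in each of 6 classes, with exact 95% intervals for counting error; the grey line marks a ratio of 1. The genes were chosen after the results were seen. All points lay above 1, and nr1d1 ranged from 6.55 in endothelial-like to 22.7 in Schwann-like cells.

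The share of cells with cell cycle transcripts was lower at day 45. At 1000 UMIs per cell, 29.3% of cells (28.0 to 30.6) at day 30 and 19.1% (18.2 to 20.0) at day 45 had at least 2 UMIs of the mitosis list, a ratio of 0.652 (0.604 to 0.703); 866 and 2677 shallower cells were left out, and the shares without thinning were 60.5% and 40.4%. In myocyte-like cells the shares were 52.9% and 25.1% (without thinning 95.4% and 86.0%), and in connective-tissue-like cells 13.8% and 9.69% (56.0% and 31.9%). The intervals of the ratio included 1 in Schwann-like (33.8% and 37.2%; 49.1% and 40.7% without thinning), stem cell-like (13.4% and 15.7%; 52.2% and 45.0%), endothelial-like (39.8% and 33.7%; 67.1% and 52.4%) and mural-like cells (33.2% and 32.8%; 77.7% and 49.9%). For stem cell-like cells the direction turned: the ratio was 1.18, 1.97 at 500 UMIs, and 0.684 (0.538 to 0.874) clustered without cell cycle genes. Fast fibre-like cells, which should not divide, had 10.3% (4 of 39 cells, 2.87 to 24.2) and 21.1% (23 of 109, 13.9 to 30.0). Their medians of depth were 3523 and 2992 UMIs. Shares at or below theirs read as background, as at day 45 in all cells, connective-tissue-like and stem cell-like cells. The myocyte-like share at day 45, 25.1%, lay within the fibre interval. Higher day 45 shares in Schwann-like, endothelial-like and mural-like cells need not mean division. By the narrow list these classes had 6 of 1112, 0 of 315 and 0 of 296 cells at day 45.

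With the narrow list the background was 0 of 39 and 0 of 109 fast fibre-like cells, which allows shares of up to 7.69% and 2.75%, and the shares of all cells were 9.89% and 0.982%, a ratio of 0.0993 (0.0760 to 0.128), or 14.2% and 2.71% without thinning. Cluster 14 takes most such cells out of the classes, so classes were also rebuilt without cell cycle genes. Of its cells, 314 at day 30 and 0 at day 45 then fell among connective-tissue-like cells. Shares by the narrow list in the rebuilt classes were 11.3% and 0.432% in connective-tissue-like, 10.3% and 0.502% in stem cell-like, 9.09% and 0.336% in mural-like, 2.22% and 0.986% in Schwann-like and 30.2% and 7.60% in myocyte-like cells. In endothelial-like cells they were 8.82% and 0 of 329 cells, which allows a share of up to 0.912%.

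**Figure D4:**
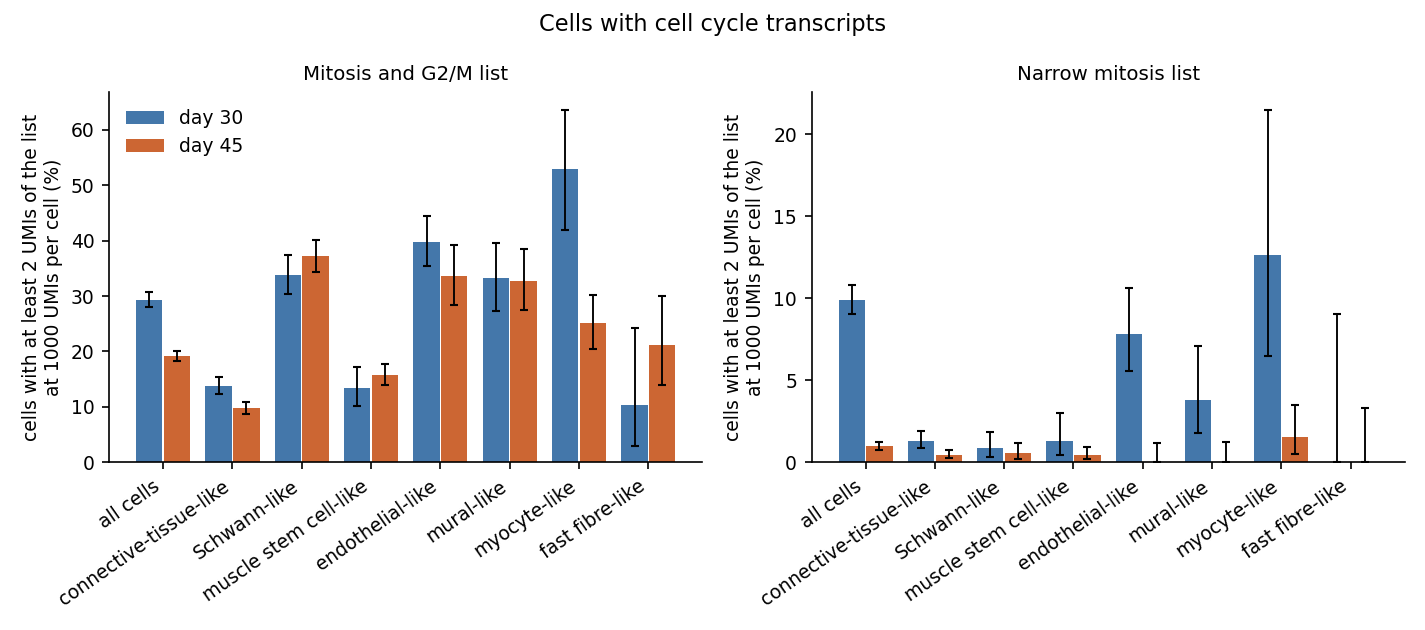
Percent of cells with at least 2 UMIs of the mitosis and G2/M list (left) and of the narrow mitosis list (right) at 1000 UMIs per cell, at day 30 and day 45, in all cells and by class; error bars are exact 95% binomial intervals for counting error. All cells had 29.3% and 19.1% by the full list and 9.89% and 0.982% by the narrow list, and fast fibre-like cells, the background, had 10.3% and 21.1% by the full list and 0 cells by the narrow one.

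The last comparison asked where the muscle lineage stood along myogenesis, taking stem cell-like, myocyte-like and fast fibre-like cells together at 1000 UMIs (515 and 1834 cells, with 79 and 385 left out). The stem cell genes pax7a or pax7b were found in 32.4% (28.4 to 36.7) at day 30 and 22.7% (20.8 to 24.7) at day 45, a ratio of 0.699 (0.583 to 0.842); within stem cell-like cells alone the shares were 38% and 28.3%, a ratio of 0.745 (0.615 to 0.906). The share with mymk, which encodes the fusion protein myomaker, was 0 of 515 cells, which allows up to 0.583%, against 25 cells or 1.36% (0.884 to 2.01); the ratio was at least 2.34 with day 30 set at that limit, with a lower 95% bound of 1.77. Shares with myf5 (28.5% and 29.6%), myod1 (4.27% and 6%) and myog (9.71% and 11.9%) had ratios whose intervals included 1. Without thinning the shares were 61.8% and 42.4% for pax7a or pax7b, 48.5% and 48.3% for myf5, 12.3% and 14.3% for myod1, 14.1% and 18.7% for myog and 2.36% and 4.73% for mymk, for which the ratio was 2.01 (1.14 to 3.80). The unthinned ratio for myog was 1.32 (1.04 to 1.69), an interval that does not include 1. The genes pax7b and myf5 are among the leading genes of cluster 2, which held 342 of 464 stem cell-like cells at day 30 and 1144 of 1749 at day 45. Within myocyte-like cells, mymk was found in 0 of 87 and 4.83% of cells at 1000 UMIs, and in 10.3% and 22.4% without thinning.

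The immune cluster 15, which should lack these genes, had 0.826% (1 of 121 cells) and 0 of 252 cells for pax7a or pax7b, 0 and 0.397% for both myf5 and myog, and 0 and 0 for myod1 and mymk, where a count of 0 allows up to 2.48% and 1.19%. Its median depths were 1785 and 1906.5 UMIs, against 2787 and 2169 in stem cell-like and 9712 and 9025 in myocyte-like cells. The day 45 share for mymk lies close to that limit, but 1 of 3024 connective-tissue-like cells (0.0331%, up to 0.184%) had mymk at day 45, with a class median of 2175.5 UMIs.

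**Figure D5:**
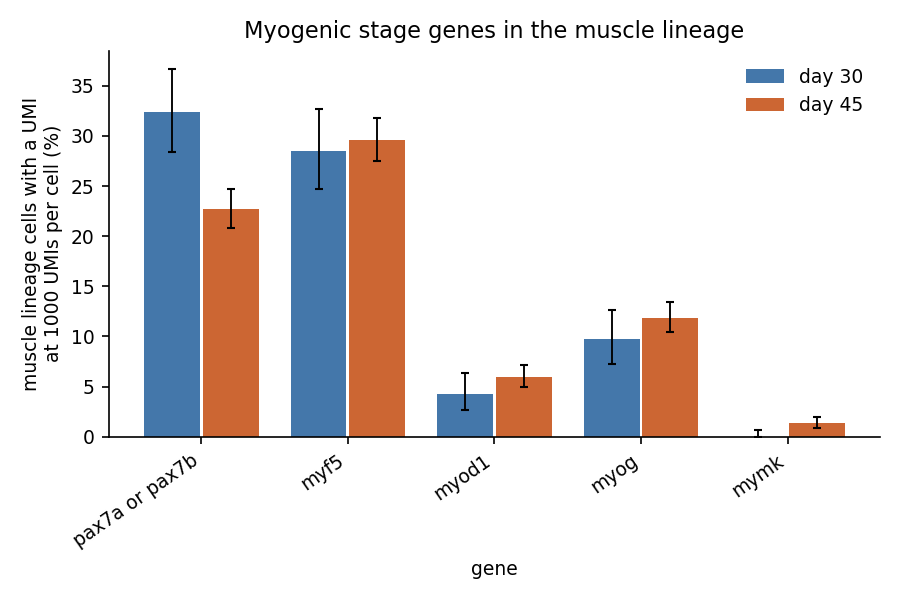
Percent of muscle lineage cells with at least 1 UMI of each myogenic gene at 1000 UMIs per cell, at day 30 (515 cells) and day 45 (1834 cells); error bars are exact 95% binomial intervals for counting error. The share with pax7a or pax7b was 32.4% at day 30 and 22.7% at day 45, and mymk was found in 0 cells at day 30 and 1.36% at day 45.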

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

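Of the values that call for caution, 5.00% of UMIs at day 30 and 7.22% at day 45 sat in features without a gene name, nearly all in 1 of them (4.71% and 6.75%), and were not used here. Several lists differed in direction between classes, and these differences were not tested. The replication list had a median log2 ratio of 0.81 in Schwann-like cells against -1.02 in connective-tissue-like, -1.67 in endothelial-like, -1.87 in mural-like and -1.72 in myocyte-like cells, with 0.16 in stem cell-like cells. The matrix list had 0.39 in Schwann-like and 0.35 in endothelial-like cells against -1.26 in myocyte-like cells, and the angiogenesis list 0.37 in myocyte-like against -0.37 in endothelial-like cells.

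For clock genes, the test of scaling was chosen after the result was seen, and the criterion of the test of sampling time was narrowed after its result was seen. If fish were sampled at different times of day, genes of the opposite clock phase should be lower at day 45. The set tested held members of the bmal (arntl), npas2, clock and nfil3 families. Its median lay above -0.25 in 4 of 6 classes and below -0.5 in 1. With any 1 gene left out it stayed above -0.25 in only 2 of 6 and below -0.5 in 0. Members went both ways: clocka and clockb were lower in all 6 classes, and nfil3-6 was higher in all 6. In connective-tissue-like cells log2 ratios ran from -1.55 for clocka to 1.25 for nfil3-6, and within the bmal family from -1.21 (arntl2) to 1.06 (arntl1a). The hour of sampling could therefore not be decided. Free RNA from 1 class was not decided. In 6 of 6 classes the output genes reached at least 0.2 times the highest class, with the lowest value, 0.353, in myocyte-like cells. Genes had to reach that same limit to be named in a class, so the choice of genes partly set this outcome. Scaling to the total is an unlikely cause, since the lowest class median was 1.95 under the trimmed mean and without the most abundant genes. The mean over cells was not part of that test. Sampling time, age and the handling of each library remain open explanations. Fish of both ages sampled at the same hour would remove only the difference in hour.

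For chaperone genes, the test of handling stress was chosen after the result was seen. Damaged cells with a high mitochondrial share are an unlikely source, since the median log2 ratio was 2.40 in cells with at most 5% mitochondrial UMIs against 2.42 in all cells. Damage that leaves this share low was not tested, and kept cells had medians of only 3.08% and 2.68%. Stress from handling or dissociation is a candidate explanation: the immediate-early list lay among the highest 2.5% of random lists in 6 of 6 classes. This list also holds heat shock genes, among them dnajb1b of the chaperone set. It can therefore be raised by the chaperone pattern itself and does not decide the question. A difference in age or rearing could give the same picture, and only libraries dissociated side by side would separate them.

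For cell cycle genes, the tests of depth by both lists, of class mix and of filters by the narrow list were chosen after the result was seen. Shallower cells at day 45 are an unlikely cause for the narrow list, since at 1000 UMIs per cell the upper bound of the ratio was 0.128; for the full list it was 0.703, but its day 45 share is at background and decides nothing. With classes built without cell cycle genes the narrow-list ratio was at most 0.103 in endothelial-like and 0.0382 in connective-tissue-like cells. A different mix of classes would not give this, but a different mix of clusters within a class could. A rebuilt connective-tissue-like cluster held 400 cells at day 30 and 0 at day 45, and another held 21 and 1142. By the full list the ratio was 0.404 in connective-tissue-like and 0.801 (0.629 to 1.02) in endothelial-like cells. There the mix of classes stays open for endothelial-like cells. Without doublet calls and the mitochondrial filter the ratio was 0.649 by the full list, which again decides nothing, and 0.0960 (0.0741 to 0.123) by the narrow list against 0.0993 with them, so filters are an unlikely cause. Less division at the older age remains open, as do differences between the fish or the preparations of the libraries.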

How the results depend on the processing

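Across 19 of the 20 alternatives, all but the narrow-list share without filters, 1909 results were compared with the main ones. Of these, 1757 stayed the same, 137 moved and 15 reversed. Counts of genes and list medians within 1.5-fold of the main value were the same. Thus 1885 lower genes in connective-tissue-like cells, clustered without cell cycle genes, counted as the same as 1257. So did an oxidative phosphorylation median of -0.06 against -0.51, in the Schwann-like cluster taken alone. All-cell counts (1232 and 1981) could not change with clustering settings, which alter only the classes. The tally is not a measure of stability. Ratios below are day 45 over day 30. No paired analysis was possible because each age had 1 library and no animals in common. The causes were not tested unless stated.

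With at least 500 genes per cell the share of mural-like cells had a ratio of 0.887, that of fast fibre-like cells 1.05, the haemoglobin list in all cells a median of -0.46 the fast sarcomere in myocyte-like cells 1.05, and acte1 there a ratio of 0.834. With at most 10% mitochondrial UMIs the share of connective-tissue-like cells was 0.774, acte1 0.118 and the mitosis median in endothelial-like cells -1.26. For acte1 the ratio was 0.216 with doublet calls kept, 0.209 at resolution 0.4 and 0.205 at resolution 1.5 (13 UMIs at day 30 in the main classes). In myocyte-like cells dynll1 (main 0.111) had 0.166 with at least 500 genes, 0.167 with at most 10% mitochondrial UMIs, 0.158 with doublet calls kept, 0.162 and 0.163 at resolutions 0.4 and 1.5 and 0.180 under the trimmed mean, and lsp1b (main 0.109) had 0.166 with doublet calls kept and 0.176 under the trimmed mean. With genes centred within each library the myocyte-like medians were -0.027 for calcium handling and -0.070 for lipid genes.

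Under the trimmed mean of M-values 153 genes were at least 2-fold lower in Schwann-like cells, 935 were higher and 247 lower in stem cell-like cells, and growth signalling in myocyte-like cells had a median of 0.56, against 0.022 without the 50 most abundant genes. With the mean over cells the Z-disc list in all cells had -0.29 and calcium handling in myocyte-like cells -0.30; 25 more results moved without reversing, among them the medians in all cells of the fast sarcomere (0.25) and haemoglobin lists (2.88), and nr1d1 in all (14.1), connective-tissue-like (14.9) and mural-like cells (6.72).

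A minimum of 20 UMIs per gene admits more genes and by construction raises the counts: 2021 higher in all cells, 1752 higher and 2376 lower in connective-tissue-like, 1358 and 836 in Schwann-like, and 1386 and 1622 in stem cell-like cells. With no minimum and 1 UMI added the counts were 5021 higher and 4341 lower in all cells, 4522 and 3979 in connective-tissue-like, 3243 and 2908 in Schwann-like, and 1759 and 5124 in stem cell-like cells.

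Thinned to 500 UMIs, the ratio of cycling shares was 0.518 in all, 1.97 in stem cell-like and 0.216 in myocyte-like cells, and with at least 1 UMI of the list it was 0.819 in all cells.

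The following were added after seeing the data. With the narrow mitosis list the ratio of cycling shares was 0.0993 in all, 0.329 in connective-tissue-like, 0.638 (0.171 to 2.39; 6 and 6 cells) in Schwann-like, 0.335 (0.0851 to 1.39; 5 and 6 cells) in stem cell-like and 0.119 in myocyte-like cells, and at most 0.121 in endothelial-like and 0.268 in mural-like cells; the genes taken out are also found in cells that do not divide. Clustered without cell cycle genes, which returns cluster 14 to other classes, the share of connective-tissue-like cells had a ratio of 0.821, of stem cell-like cells 1.91 and of fast fibre-like cells 1.08, and growth signalling in myocyte-like cells a median of 0.20. There the medians of mitosis were -5.23 in connective-tissue-like and -2.82 in mural-like cells and of replication -2.76 in connective-tissue-like cells, those of the fast sarcomere and matrix in myocyte-like cells 1.25 and -0.50. Ratios were 0.0460 for mxd3 in connective-tissue-like, 5.28 for tuba8l2 in stem cell-like and 0.0923 for mxra5a, 0.249 for dynll1 and 0.873 for acte1 in myocyte-like cells, and the cycling share 0.404 in connective-tissue-like and 0.684 in stem cell-like cells. The cycling share without doublet calls and the mitochondrial filter had a ratio of 0.649 by the full list and 0.0960 by the narrow list.

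Without connective-tissue-like clusters mostly of 1 library, also added after seeing the data, 14 of 29 results moved and 0 reversed: 628 genes were lower, the medians were -0.56 for mitosis and 1.54 for antigen presentation, and ratios were 39 for si:ch211-132b12.7, 16.7 for nr1d1, 10.3 for znf395b, 13.5 for si:dkey-211g8.8, 14 for c4, 11.2 for cry2, 7.18 for ciarta, 7.55 for dnajb1b, 0.116 for pdia4, 0.156 for manf and 0.129 for arpc5a. In Schwann-like cluster 6 alone, added likewise, 19 of 27 results moved and 1 reversed: 146 genes were higher, and the medians were 0.58 for immediate-early, 0.47 for interferon and -0.20, the reversal, for growth signalling genes. Ratios there were 17.3 for nr1d1, 11.4 for si:dkey-211g8.8, 4.2 for bag3, 1.83 for dnaja, 6.20 for per1b, 5.59 for cry2, 4.82 for pim2, 2.57 for hspbp1, 3.00 for zfand2a, 0.612 for both lig1 and ube2na, 0.114 for si:ch211-156j16.1 and 0.759 for gstt1b.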

Other observations

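Transcripts of the apolipoprotein gene apoeb came from few cells. All cells held 262 UMIs at day 30 and 4542 at day 45, and 46 of the 277 day 45 cells of Schwann-like cluster 17 held 4087 of them, or 90%, with 1555 in a single cell. The 43 day 45 cells with at least 5 UMIs of apoeb also held 182 UMIs of apoc1, another apolipoprotein gene. They held 45 of foxd3, a neural crest transcription factor gene, 103 of ngfrb and 119 of nes. Each of these, apoc1 included, was found in 18 to 21 of the cells. They also held 92 of the myelin gene mbpa and 48 of mpz, and 0 of csf1ra and c1qa. The genes apoeb, apoc1, csf1ra and c1qa are all on the macrophage marker list, whose other members were not counted in these cells. At day 30, 14 cells had that many UMIs of apoeb, and cluster 17 had 56 cells with 7 UMIs. These cells were picked out after the values were seen.

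Fast fibre-like cells, 43 at day 30 and 135 at day 45, were too few at day 30 for a comparison. At day 30 some of them held transcripts of slow or cardiac contractile genes: myl2a in 13 cells, tnnc1b in 16, tnni1b in 10, tpm2 in 20 and myl10 in 17, against 2, 6, 0, 4 and 5 cells at day 45. Of the day 30 UMIs, 87.1% of myl2a, 83.1% of tnni1b and 69.1% of myl10 were in these cells, and 26.5% of tpm2, which 586 of all cells held; at day 45 fibres held 4.61% of the tpm2 UMIs. The fast genes actc1b and pvalb1 had 22016.8 and 5760.7 CPM at day 30 and 41383.1 and 18177.0 at day 45. These genes were also chosen after the values were seen.

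Some genes were named in more than 1 class. The cryptochrome gene cry3b was among the genes lowest at day 45 in connective-tissue-like, stem cell-like, endothelial-like and mural-like cells, while the cryptochrome gene cry2 was among those highest in connective-tissue-like and Schwann-like cells. The matrix-related gene mxra5a was lower in both stem cell-like and myocyte-like cells. The interferon list had a positive median in all 6 classes, from 0.82 in endothelial-like to 1.36 in mural-like cells. Nuclear genes of oxidative phosphorylation had a negative median in all 6, from -1.25 in mural-like to -0.51 in Schwann-like cells. In Schwann-like cluster 6 alone the median was -0.06.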
